A study of Rattus norvegicus with 62 samples.

How the data were processed

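Liver RNA of 62 samples was hybridised by the authors to Affymetrix rat arrays; the array model and the scaling target are not given in the sources used here. The deposited values are linear MAS5 signal intensities, computed by the authors with MAS5 5.0 per the submitters' processing notes. The 2% trimmed mean of each array lay between 500.23 and 500.27, so the arrays were used as scaled by the authors. The table held 31099 probe sets and no missing value, with signals from 0.0673 to 82817. Per the labels, an initiator was given for 1 or 2 weeks and withdrawn for 2 weeks, and water with 500 ppm of phenobarbital followed for 6 weeks, with hepatectomy 1 week after it began. The 7 treatments at each of the 2 weeks make 14 groups of 4 or 5 arrays. Groups and doses were taken from the labels, and raw intensity files were not used here.

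Of the probe sets, 57 were controls, 20826 had 1 gene symbol, 436 had several and 9780 had none; those with 1 symbol covered 14217 genes. Symbols came from the table that pairs the probes with genes, and 20758 were checked against the reference table by gene identifier, with 0 updates. No genome coordinates were used. Probe sets with no or several symbols stayed out of the tests by gene. An offset of 25, 5% of the median trimmed mean, was added before the log2 step. A probe set was kept if its signal reached 100, 20% of that mean, on at least 4 arrays of the fit. For each gene the probe set with the highest mean was used, which left 10491 genes at 5w, 10546 at 10w and 10910 in the fit of both weeks. The number of arrays limits the precision.

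Each comparison was a contrast in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit and eBayes with trend), two-sided, at a Benjamini-Hochberg adjusted p of 0.05 over the genes tested. Effects within a week were fitted on the 31 arrays of that week. Changes between weeks, and differences of an effect between weeks, were fitted on all 62 arrays. The groups, contrasts, filter, alternatives, 32 gene lists of liver pathways and cell types and the rule for naming genes were fixed before the data were examined. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. With the preset correlation 171 of 704 list tests passed, and with the estimated one 25, each of which was among the 171. The lists described in the text were picked from these calls after their results were seen. Members of a list were also counted with p adjusted over the list alone.

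The rule for naming genes took, for each comparison within a week, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap in any animal. It took the 5 largest of each for comparisons that involve time, up to 4 members with the smallest p of a list that is described, and a fixed set of liver, focus, p53 and cell cycle markers whether or not they passed. Genes outside the rule are said to be so where they are named.

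The labels say that both weeks' samples came from the same animals. As a check of the numbering, correlations of residuals were computed: in 31 pairs with the same treatment and number, r lay between 0.228 and 0.405, against 0.005 to 0.155 for other numbers of the same treatment and array set. Among the arrays of its treatment at the other week, each of 62 arrays correlated best with its own number. Arrays of other treatments were left out of that ranking. With the same number, week and array set they reached 0.301. The animal was used as a block in an alternative, with a consensus correlation of 0.315. Within a week the same number in different treatments names different animals. All 4 such pairs correlated above 0.1 in each comparison within a week but MP and APAP at 5w, with 3 and 2 of 4. Most of this went with the array set: in other treatments of the same week, different numbers of the same set correlated at a median of 0.112 (145 of 240 pairs above 0.1), against 0.141 for the same number (142 of 170). The replicate number as a block was run as an alternative for every comparison. The array sets were read from the first component of the residuals, after the files had been seen.

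The steps were tested on simulated data. For PB at 10w (10546 genes) 88 of 100 simulated 2-fold changes and 99 of 100 simulated 4-fold changes were recovered, and 11 of 198 calls were false. For MP at 10w (10546 genes) the numbers were 86 and 99 of 100, with 1 of 186 calls false, and for PB by time (10910 genes) 63 and 91 of 100, with 0 of 154 false. A simulated list of 20 genes shifted by 0.5 was found in each of these 3 comparisons, and 0 of the other lists were called. The simulated genes varied independently of each other and without array sets. These numbers therefore do not show how often genes or lists are falsely called when genes are correlated.

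The alternatives were no offset, no filter, quantile normalization, all probe sets, the replicate block, only the groups compared, the animal as a block, an estimated correlation for lists and leaving out each array. Those by array set were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, checks and plots. For called genes named in the text, 42 other probe sets of 27 genes passed the filter, of which 39 had the same sign and 3 the opposite one; 13 of the 39 passed as well.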

Results

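Hepatic transcript levels were measured on 62 microarrays from male Crj:CD(SD)IGS rats, an outbred Sprague-Dawley stock. Animals received an initiator or its methylcellulose vehicle (MC), and after a pause they drank phenobarbital (PB), a liver tumour promoter, or plain water. The initiators were diethylnitrosamine at 3 mg/kg (DEN3) or 30 mg/kg (DEN30), thioacetamide at 45 mg/kg (TAA), methapyrilene at 100 mg/kg (MP) and acetaminophen at 1000 mg/kg (APAP). Each animal gave a liver sample at partial hepatectomy (5w) and another at the end (10w). At each week there were 5 animals in each of the DEN3/PB, TAA/PB and MP/PB groups and 4 in each of the MC/water, MC/PB, DEN30/PB and APAP/PB groups. The median signal per array lay between 99.3 and 125.7, at a trimmed mean near 500.26, and between 49.87% and 54.84% of probe sets exceeded the signal minimum. The number of arrays limits the precision.

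In all 14 groups the arrays fell into a pair of sets, with 30 arrays in set 1 and 32 in set 2, and the first component of the variation within groups, 14.8% of it, separated them. Between 2 and 3 arrays of each group lay in each set. Counts and most list medians are therefore given within each set beside the pooled ones. Named genes that passed are given within each set where these values differed by more than 1.5 times, which 28 of 123 did. All changes below are differences of log2(signal + 25) with their standard error, a scale that understates changes from low signals. In 13 of 123 named results that passed, every array of the lower group lay under the signal minimum of 100. This holds for Abcc3 and Car1 under phenobarbital at both weeks, Sema3c there at 5w and Ddit4l at 10w, for Adam8 and Pvt1 after both doses of diethylnitrosamine, for Pbsn, and for Cyp2a3 and Pla2g2a between the weeks. A fold for these is a lower bound, with signals under 100 set to 100. Where no fold is printed below, the bound was 7.99 for Abcc3 at 5w, 4.82 for Ddit4l and 2.78 for Sema3c. It was 2.27 for Adam8 after DEN30 and 2.05 for Pvt1 after DEN3. The bound was small for Car1 (1.8 at 5w, 1.43 at 10w) and for Pvt1 after DEN30 (1.73). For Pla2g2a it was 1.35, and 1 array of its higher group also lay under the minimum. Adjusted p values come from limma with the Benjamini-Hochberg correction.

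The first question was what phenobarbital did to the liver without an initiator. After 1 week of phenobarbital, the liver held far more transcript of drug-metabolising enzymes and exporters and far less of the collagen cross-linking enzyme Lox. Aldh1a1, a retinaldehyde dehydrogenase, rose by 4.08 ± 0.32, or 16.9-fold (n = 4 per group, limma adjusted p = 5.31e-10). Abcc3, an exporter of conjugated bile acids and drugs, rose by 3.92 ± 0.32, and the carboxylesterase Ces2c by 3.37 ± 0.27. The glutathione transferase Gsta3 rose by 3.08 ± 0.36, its relative Gstm3 by 2.79 ± 0.44 and the glucuronosyltransferase Ugt2b1 by 2.32 ± 0.14. Sema3c, a secreted guidance protein, rose by 2.25 ± 0.38, and the stress-inducible Gadd45b by 1.87 ± 0.36. Lox fell by 4.42 ± 0.31 on the log2 scale, from 11.42 ± 0.74 (SD, n = 4) in MC/water to 7 ± 0.35 (SD, n = 4) in MC/PB. In each of these genes all 4 treated animals lay on the same side of all 4 controls, which the rule for naming genes required. The same held for 675 of the 10491 genes tested at 5w.

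Of the 21 measured members of the list of phenobarbital-inducible metabolism genes, 13 rose and none fell at 5w (16 higher and 1 lower adjusted over the list alone), and the list rose as a whole (camera adjusted p = 2.27e-35, adjusted p = 6.48e-05 with an estimated correlation, median 0.72, 0.64 and 0.79 in the sets). Its members Ephx1, the microsomal epoxide hydrolase, and Cyp3a9 rose by 0.72 ± 0.10 and 1.58 ± 0.38. Ephx1 is counted in the NRF2 list below as well. Cyp3a2 did not pass, at 0.10 ± 0.07 (limma adjusted p = 0.674), with a high signal in both groups (mean 14.98 in MC/water and 15.08 in MC/PB). Cyp2b1 and Cyp2b2 had no probe set with 1 gene symbol and were not tested by gene. A Cyp2b probe set that matches several genes was higher by 3.69 ± 0.29 when all probe sets were tested (limma adjusted p = 8.39e-10). Of 18 targets of the oxidative stress regulator NRF2, 5 rose (5 adjusted over the list alone), with Nqo1 at 1.31 ± 0.20, Akr7a3 at 0.97 ± 0.21 and Mgst2 at 0.62 ± 0.12 (list adjusted p = 3.92e-09, adjusted p = 0.000438 with an estimated correlation, median 0.41, 0.30 and 0.46 in the sets). Of 20 cholesterol synthesis genes 3 rose (7 adjusted over the list alone), Msmo1 by 1.33 ± 0.25, Fdft1 by 0.48 ± 0.11 and Sqle by 1.02 ± 0.27. That list's call (adjusted p = 2.82e-08, median 0.33, 0.33 in both sets) was lost at adjusted p = 0.145 with an estimated correlation.

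Periportal genes were lower as a list at 5w (2 of 19 fell, 6 adjusted over the list alone, adjusted p = 8.60e-08, adjusted p = 0.0435 with an estimated correlation, median -0.20, -0.22 and -0.31 in the sets). The gluconeogenic enzyme Pck1 fell by 0.72 ± 0.15 and the serine dehydratase Sds by 1.38 ± 0.33. Perivenous genes were lower as a list too (1 of 14 rose and 2 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.0185, median -0.31, mean -0.04), a call lost at adjusted p = 0.145 with an estimated correlation. Hepatocyte functions were lower (2 of 26 fell, the same number adjusted over the list alone, adjusted p = 0.000222, median -0.12), a call lost at adjusted p = 0.156 with an estimated correlation. Liver genes biased to females were higher as a list (1 of 6 rose, 3 adjusted over the list alone, adjusted p = 0.000222, adjusted p = 0.00338 with an estimated correlation, median 0.93, 0.61 and 1.12 in the sets). Cyp2c7 and Cyp3a9 among the 6 also belong to the phenobarbital-inducible list, and Cyp3a9 was the 1 member that passed. The other 4 stood between 0.78 and 1.06 without passing. The kinase Sgk1 fell by 1.56 ± 0.36, the carbonic anhydrase Car1 by 1.45 ± 0.31, the dicarboxylate transporter Slc13a3 by 1.33 ± 0.28 and the monooxygenase Fmo1 by 1.15 ± 0.28. The chemokine Cxcl9 rose by 1.68 ± 0.28. The sets differed in size of change for Car1 (-0.85 in set 1, -2.05 in set 2), Fmo1 (-0.66, -1.65), Sds (-1.66, -1.10), Ephx1 (0.50, 0.94) and Cyp3a9 (1.92, 1.24). The cell cycle list was higher (1 of 36 rose and 1 fell, the same numbers adjusted over the list alone, adjusted p = 0.000536, median 0.26, 0.36 and 0.17 in the sets), a call lost at adjusted p = 0.383 with an estimated correlation. Mki67, a marker of cycling cells, differed by 0.46 ± 0.24 (limma adjusted p = 0.504). Gstp1, the placental glutathione transferase of preneoplastic foci, differed by -0.21 ± 0.30 (limma adjusted p = 0.891), and the AhR target Cyp1a2 by -0.55 ± 0.25 (limma adjusted p = 0.403).

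In all, 131 of 10491 genes passed at 5w, 87 higher and 44 lower, and 35 changed at least 2-fold. Within set 1 alone 18 passed and within set 2 alone 20, and 166 passed with set as a block. The count was 84 without 5w MC/water replicate 4 and 65 without 5w MC/PB replicate 1, and 78 when only the compared groups were fitted.

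By 10w the response to phenobarbital held 238 of 10546 genes, 168 higher and 70 lower, with 88 changed at least 2-fold. Abcc3 rose by 5.49 ± 0.34, at least 18.2-fold (n = 4 per group, limma adjusted p = 2.61e-12; MC/water signals 7.19 to 75.3), Gsta3 by 4.38 ± 0.31 and Aldh1a1 by 4 ± 0.20. Ces2c rose by 3.52 ± 0.32, Gstm3 by 2.90 ± 0.38, Ugt2b1 by 2.75 ± 0.20 and Gadd45b by 2.46 ± 0.35. The lipoprotein lipase gene Lpl rose by 3.49 ± 0.41 and the mTOR inhibitor Ddit4l by 2.98 ± 0.47. Lox fell by 3.29 ± 0.30, and the male-specific lipocalin Obp3 fell by 2.56 ± 0.56. The ornithine aminotransferase Oat fell by 1.69 ± 0.43, Lrtm2 by 1.79 ± 0.33, the organic anion transporter Slc22a8 by 1.49 ± 0.38, the tumour suppressor Rb1 by 1.44 ± 0.22 and Car1 by 1.53 ± 0.32.

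Of the same 21 phenobarbital-inducible genes, 15 rose at 10w (18 higher and 1 lower adjusted over the list alone, list adjusted p = 2.65e-41, adjusted p = 1.26e-05 with an estimated correlation, median 0.98, 0.97 and 1.06 in the sets). Of 18 NRF2 targets 6 rose (13 adjusted over the list alone, adjusted p = 2.12e-18, adjusted p = 0.00307 with an estimated correlation, median 0.91, 0.80 and 0.95 in the sets), with Akr7a3 at 2.29 ± 0.28, Nqo1 at 1.61 ± 0.26, Mgst2 at 1.06 ± 0.12 and Ephx1 at 0.90 ± 0.11. Ephx1 is also a member of the phenobarbital-inducible list, so these lists are not fully separate. Of 20 cholesterol synthesis genes 8 rose (12 adjusted over the list alone), among them Msmo1 at 1.42 ± 0.27, Idi1 at 1.22 ± 0.27, Mvd at 0.63 ± 0.13 and Fdft1 at 0.59 ± 0.13. The cholesterol list's call (adjusted p = 5.14e-12, median 0.60, 0.79 and 0.39 in the sets) was lost at adjusted p = 0.0999 with an estimated correlation. Fatty acid oxidation genes went both ways. Of 24, the scavenger receptor Cd36 and the pantetheinase Vnn1 rose by 1.29 ± 0.25 and 1.33 ± 0.35, while the carnitine transferase Cpt1a fell by 1.10 ± 0.28 and Cyp4a1 by 0.78 ± 0.20 (3 higher and 3 lower adjusted over the list alone). That list was lower as a whole (adjusted p = 0.0321, median -0.17, -0.21 and -0.11 in the sets), a call lost at adjusted p = 0.466 with an estimated correlation. Female-biased genes were higher as a list (1 of 7 rose, the same number adjusted over the list alone, adjusted p = 0.00443, adjusted p = 0.0356 with an estimated correlation, median 0.75, 0.99 and 0.55 in the sets), with the drug exporter Abcb1a at 1.56 ± 0.34. Among the 7, Cyp2c7 and Cyp3a9 also belong to the phenobarbital-inducible list, and the others stood between 0.32 and 1.56. Periportal genes were lower as a list with no member passing (3 adjusted over the list alone, adjusted p = 0.0110, median -0.11, -0.16 and -0.12 in the sets), a call lost at adjusted p = 0.518 with an estimated correlation. The sets differed for Gadd45b (3.19 in set 1, 1.74 in set 2), Slc22a8 (-1.12, -1.85), Msmo1 (2.01, 0.84), Idi1 (1.65, 0.80), Fdft1 (0.78, 0.4), Cd36 (1.56, 1.01) and Abcb1a (1.97, 1.15). Gstp1 differed by 0.25 ± 0.41 and Cyp3a2 by 0.21 ± 0.10 (limma adjusted p = 0.870 and 0.308).

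Of the genes tested at both weeks, 61 rose at both and 13 fell at both, against 1.42 and 0.299 for independent samples, and none changed in opposite directions. The fold changes of the weeks correlated at r = 0.544 across 10312 genes, against 0.255 in simulated unchanged groups; the same animals gave both samples, and genes are not independent replicates. At 10w 54 genes passed within set 1, 34 within set 2 and 370 with set as a block, and the replicate block gave 394. The count was 150 without 10w MC/water replicate 1, 147 without 10w MC/water replicate 2, 141 without 10w MC/PB replicate 1 and 152 without 10w MC/PB replicate 2.

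**Figure D1:**
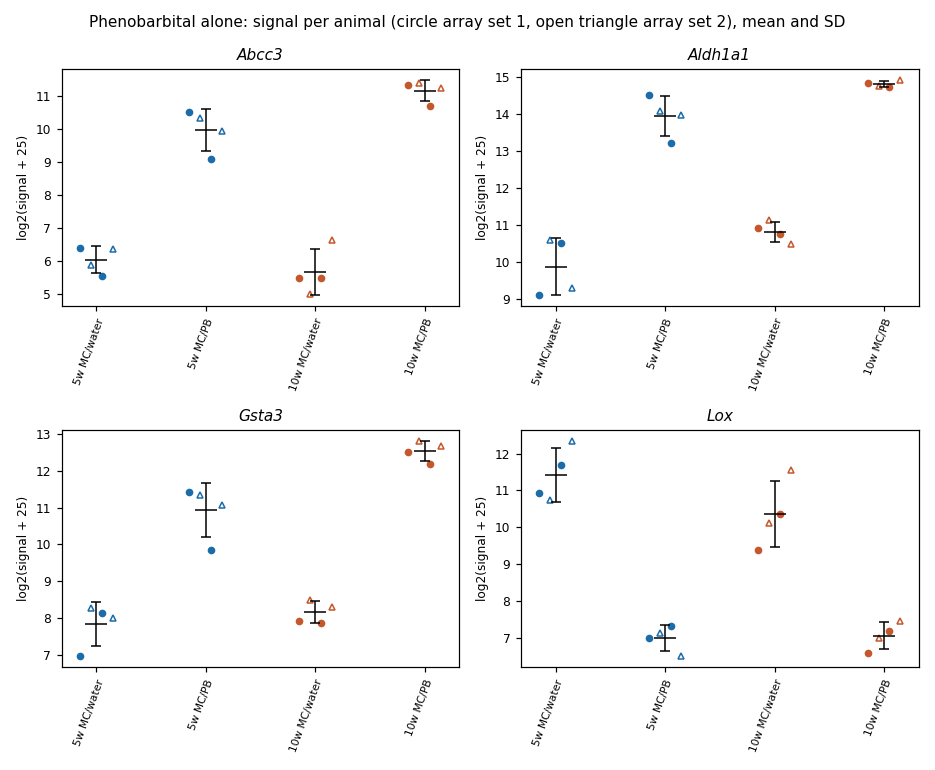
Signal of Abcc3, Aldh1a1, Gsta3 and Lox per animal, as log2(signal + 25), in the MC/water and MC/PB groups at both weeks (n = 4 each, bars, mean and SD, blue 5w, orange 10w, circles array set 1, open triangles array set 2). Abcc3 lay between 5.01 and 6.65 in the MC/water animals at 10w and between 10.68 and 11.39 in the MC/PB animals.

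The next question was what each initiator left behind in livers under phenobarbital, against MC/PB. At the low dose of diethylnitrosamine, Adam8, a membrane protease, rose by 2.15 ± 0.25, at least 2.65-fold, at 5w (n = 5 and 4, limma adjusted p = 1.84e-05; MC/PB signals 43.5 to 54.6), and the long non-coding RNA Pvt1 by 1.36 ± 0.21. The proton pump subunit Atp6v1d rose by 0.68 ± 0.12, and the nucleotide synthesis enzyme Prps2 fell by 0.76 ± 0.15 (-0.90 in set 1, -0.59 in set 2; its other probe sets -0.54 and -0.12). Targets of p53 were higher as a list (none of 16 passed over all genes, 5 rose adjusted over the list alone, adjusted p = 2.63e-05, adjusted p = 0.00152 with an estimated correlation, median 0.13, 0.21 in both sets). Its members Cdkn1a, a cell cycle inhibitor, at 1.02 ± 0.20, Mdm2, the ubiquitin ligase of p53, at 0.52 ± 0.12, and Ccng1 at 0.61 ± 0.15 had adjusted p of 0.0526, 0.0991 and 0.175 by limma. Cholesterol synthesis genes were lower as a list (none of 20 passed, 7 fell adjusted over the list alone, adjusted p = 6.80e-11, median -0.32, -0.38 and -0.13 in the sets), a call lost at adjusted p = 0.224 with an estimated correlation. Gstp1 differed by 0.39 ± 0.28 and Ggt1, the gamma-glutamyltransferase of preneoplastic foci, by -0.14 ± 0.30 (both limma adjusted p = 0.999). The 4 genes were the whole count. Set 1 alone called 0 genes and set 2 alone 2, none of them among the 4, and the count was 6 with set as a block and 8 with the replicate block. It was 0 with only the compared groups, and 2 without 5w MC/PB replicate 1 or without 5w DEN3/PB replicate 4.

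At 10w the DEN3 count was 2, with Stard8 up by 0.81 ± 0.15 (0.59 in set 1, 1.02 in set 2) and the glucosyltransferase Poglut2 down by 0.67 ± 0.12 (n = 5 and 4; both limma adjusted p = 0.0438). Preneoplastic focus markers were higher as a list (none of 12 passed, 1 adjusted over the list alone, adjusted p = 0.000849, adjusted p = 0.0179 with an estimated correlation, median 0.34, 0.53 and 0.15 in the sets). Gstp1 differed by 0.90 ± 0.39, Ggt1 by 0.33 ± 0.30 and the glutathione peroxidase Gpx2 by 1.67 ± 0.89 (each limma adjusted p = 1). The MC/PB mean of Gpx2 was raised by 10w MC/PB replicate 2, at 10.15 against 5.86 to 6.26 in the others, so that the difference was over 1.5 times larger without it, still not passing. The cholesterol list was lower (3 of 20 adjusted over the list alone, adjusted p = 1.49e-11, median -0.34, -0.48 and -0.07 in the sets), a call lost at adjusted p = 0.226 with an estimated correlation. Neither set alone gave a called gene, the set block gave 2 and the replicate block 0, and the count was 0 or 1 without any single array.

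At the high dose, DEN30 livers carried more Gstp1 at both weeks. At 5w Gstp1 rose by 1.58 ± 0.30, or 2.99-fold (n = 4 per group, limma adjusted p = 0.0170), Lox by 2.07 ± 0.31, Adam8 by 1.93 ± 0.26, and the glutamate receptor subunit Gria3 by 1.47 ± 0.29. The galectin ligand Lgals3bp rose by 1.37 ± 0.23, Slc16a6 by 1.22 ± 0.23, Pvt1 by 1.11 ± 0.22, the protein kinase A inhibitor Pkia by 1.09 ± 0.18, the transcription factor Sox4 by 0.91 ± 0.17 and cytoglobin, Cygb, by 0.73 ± 0.15. The elastase Cela1 fell by 1.31 ± 0.26 and Cd36 by 0.97 ± 0.20. Within set 1 Gstp1 stood at 2.23 and within set 2 at 0.93 (limma adjusted p = 0.00101 and 0.188). Its call was lost with only the compared groups (adjusted p = 0.345) and without 5w MC/PB replicate 3 or 4 or 5w DEN30/PB replicate 1 or 3. The adjusted p ran from 0.000138 to 0.345 over the alternatives that kept all arrays or 1 set. Other probe sets stood at 1.28 for Lox, 0.39 for Slc16a6 and 0.35 to 0.57 for Sox4 (limma adjusted p from 0.351 to 0.950). The sets also differed for Lgals3bp (1.09, 1.65), Pvt1 (1.45, 0.78), Cygb (0.55, 0.92), Cela1 (-1.03, -1.59) and Cd36 (-1.35, -0.59). Focus markers were higher as a list (1 of 13 rose, 8 adjusted over the list alone, adjusted p = 9.14e-10, adjusted p = 1.54e-05 with an estimated correlation, median 0.72, 1.07 and 0.55 in the sets). Its member Gpc3, an oncofetal glypican, stood at 1.36 ± 0.31 and Ggt1 at 0.72 ± 0.31 (limma adjusted p = 0.0970 and 0.755). Extracellular matrix genes were higher as a list (1 of 26 rose, 4 adjusted over the list alone, adjusted p = 3.54e-11, median 0.39, 0.27 and 0.45 in the sets). This call was lost at adjusted p = 0.0649 with an estimated correlation. Col1a1, the main fibrillar collagen chain, stood at 0.67 ± 0.25 and the gelatinase Mmp2 at 0.78 ± 0.18 (limma adjusted p = 0.576 and 0.0970). Of the 12 genes 1 passed in set 1 and 0 in set 2, and the count was 12 with set as a block. The count was 6 without 5w MC/PB replicate 3, 2 without 5w MC/PB replicate 4, 5 without 5w DEN30/PB replicate 2, 4 without 5w DEN30/PB replicate 3, and 4 with only the compared groups.

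At 10w Gstp1 rose by 2.65 ± 0.41, or 6.29-fold (n = 4 per group, limma adjusted p = 0.00494), from 10.02 ± 0.52 (SD) in MC/PB to 12.67 ± 1.15 (SD). Within set 1 it stood at 3.37 and within set 2 at 1.93 (limma adjusted p = 0.0190 and 0.463). The call was lost with only the compared groups (adjusted p = 0.1) and without 10w MC/PB replicate 4 or 10w DEN30/PB replicate 1. Its adjusted p ran from 0.00103 to 0.463 over the alternatives that kept all arrays or 1 set. Ggt1 rose by 1.65 ± 0.31 and the interleukin 13 decoy receptor Il13ra2 by 1.08 ± 0.19 (0.84 in set 1, 1.32 in set 2), and no other gene passed. The call of Ggt1 (adjusted p = 0.0457) was lost without an offset or filter, under quantile normalization, with all probe sets, with the replicate block and in each set alone. Its adjusted p ran from 0.0342 to 0.463 over these and the other alternatives that kept all arrays or 1 set. Focus markers were higher as a list (2 of 12 rose, 8 adjusted over the list alone, adjusted p = 8.43e-14, adjusted p = 1.06e-06 with an estimated correlation, median 0.93, 1.10 and 0.72 in the sets). Among them, the aldose reductase Akr1b8 stood at 2.46 ± 0.53, the imprinted RNA H19 at 1.09 ± 0.30 and alpha-fetoprotein, Afp, at 0.53 ± 0.17 (limma adjusted p = 0.143, 0.505 and 0.685). Cell cycle genes were higher as a list with no member passing, over all genes or adjusted over the list alone (adjusted p = 5.01e-13, median 0.63, 0.75 and 0.40 in the sets), a call lost at adjusted p = 0.231 with an estimated correlation. Mki67 stood at 0.86 ± 0.48, the mitotic kinase Cdk1 at 1.03 ± 0.40 and cyclin B1, Ccnb1, at 0.82 ± 0.43 (limma adjusted p = 0.981, 0.887 and 0.981). Extracellular matrix genes were higher as a list (0 of 25 passed, 4 adjusted over the list alone, adjusted p = 6.73e-10, median 0.39, 0.18 and 0.58 in the sets). The call was lost at adjusted p = 0.0895 with an estimated correlation. Fatty acid oxidation genes were lower as a list (none of 24 passed, none adjusted over the list alone, adjusted p = 1.05e-08, adjusted p = 0.0199 with an estimated correlation, median -0.20, -0.23 and -0.19 in the sets), with Decr1 at -0.38 ± 0.13 and Cd36 at -0.79 ± 0.25 (limma adjusted p = 0.752 and 0.685). Set 1 alone called 2 genes, 1 of them among these 3. Set 2 alone called 1, not among them, and the set block called 3. The count was 0 without 10w MC/PB replicate 4 or without 10w DEN30/PB replicate 1, and 1 without 10w MC/PB replicate 1, 10w MC/PB replicate 2 or 10w DEN30/PB replicate 2.

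Gstp1 and Ggt1 were also compared between initiators with two-sided exact permutation tests, 12 in all, adjusted together and chosen after the results above were seen. The permutations did not keep the array sets apart, so their p values do not allow for a difference between the sets. Gstp1 in DEN30/PB at 10w stood at 13.54 and 13.73 in set 1 and at 12.04 and 11.38 in set 2. At 5w it stood at 11.98 and 12.51 in set 1 and at 10.63 and 10.42 in set 2. At 10w Gstp1 was higher in DEN30/PB than in TAA/PB by 2.53, MP/PB by 2.81 and APAP/PB by 2.85 (exact permutation p = 0.00794, 0.00794 and 0.0286, the smallest these group sizes allow, adjusted p = 0.0238, 0.0238 and 0.0429). At 5w the differences were 1.33, 1.31 and 1.58 (exact permutation p = 0.00794, 0.0159 and 0.0286, adjusted p = 0.0238, 0.0318 and 0.0429). Ggt1 at 10w was higher in DEN30/PB by 1.18 than in TAA/PB and by 1.48 than in MP/PB (exact permutation p = 0.00794 and 0.0159, adjusted p = 0.0238 and 0.0318). Against APAP/PB it differed by 1.18 (exact permutation p = 0.0857, adjusted p = 0.114). At 5w Ggt1 differed by 0.36, 0.34 and 0.31 in the same order (exact permutation p = 0.294, 0.198 and 0.286, adjusted p = 0.294, 0.238 and 0.294).

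**Figure D2:**
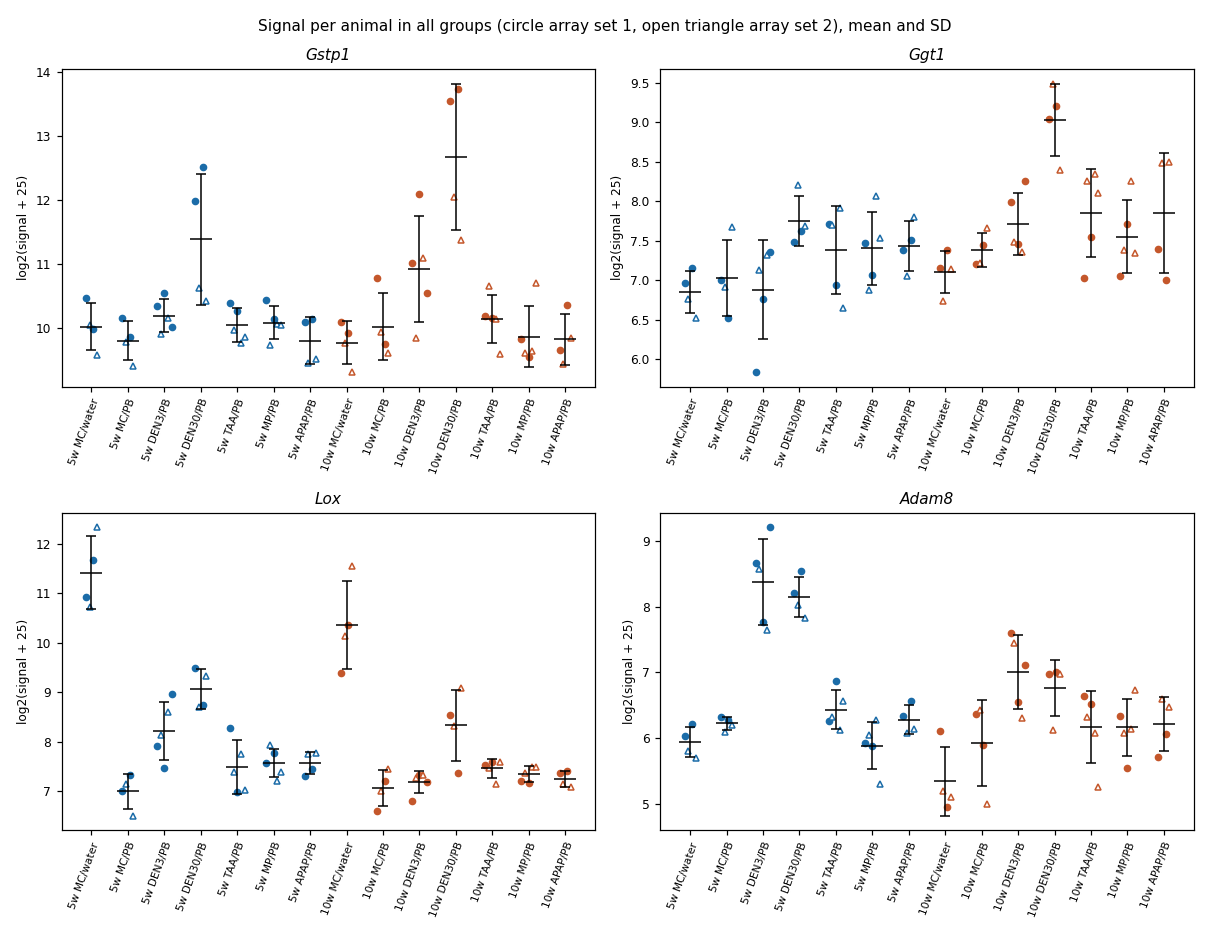
Signal of Gstp1, Ggt1, Lox and Adam8 per animal, as log2(signal + 25), in all 14 groups (n = 4 or 5, bars, mean and SD, blue 5w, orange 10w, circles array set 1, open triangles array set 2). Gstp1 at 10w lay between 11.38 and 13.73 in DEN30/PB and between 9.61 and 10.78 in MC/PB.

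The dose question was tested as DEN30/PB against DEN3/PB. At 5w the higher dose carried less Cela1, which fell by 1.47 ± 0.25 (n = 4 and 5, limma adjusted p = 0.0204), the 1 gene called. Focus markers were higher at the higher dose as a list at 5w (none of 13 passed, 3 adjusted over the list alone, adjusted p = 1.69e-07, adjusted p = 0.000124 with an estimated correlation, median 0.53, 0.59 and 0.50 in the sets), with Gstp1 at 1.19 ± 0.28, Akr1b8 at 1.55 ± 0.42 and Ggt1 at 0.86 ± 0.30 (limma adjusted p = 0.212, 0.472 and 0.730). Targets of p53 were lower (none of 16 passed, 2 adjusted over the list alone, adjusted p = 4.10e-05, adjusted p = 0.00105 with an estimated correlation, median -0.26, -0.12 and -0.27 in the sets), with Cdkn1a at -0.66 ± 0.20 and Mdm2 at -0.35 ± 0.12 (limma adjusted p = 0.668 and 0.730). Extracellular matrix genes were higher as a list (none of 26 passed, 7 adjusted over the list alone, adjusted p = 2.63e-10, median 0.31, 0.38 and 0.39 in the sets), a call lost at adjusted p = 0.0516 with an estimated correlation. Biliary and progenitor markers were higher (none of 8 passed, none adjusted over the list alone, adjusted p = 0.000305, adjusted p = 0.0199 with an estimated correlation, median 0.36, 0.23 and 0.29 in the sets). Each set alone called 1 gene, not Cela1, the set block 5 and the replicate block 2. No gene was called without 5w DEN3/PB replicate 2, 5w DEN3/PB replicate 5, 5w DEN30/PB replicate 2 or 5w DEN30/PB replicate 3. There were 2 without 5w DEN3/PB replicate 1, 5w DEN3/PB replicate 3 or 5w DEN30/PB replicate 4.

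At 10w limma called 0 genes between the doses, with 453 at an unadjusted p under 0.05, and 0 in each set alone and with either block. The exception was 1 gene without 10w DEN30/PB replicate 4. Focus markers were higher as a list (none of 12 passed, 4 adjusted over the list alone, adjusted p = 2.73e-06, adjusted p = 0.000812 with an estimated correlation, median 0.34, 0.43 and 0.52 in the sets), with Gstp1 at 1.75 ± 0.39, Ggt1 at 1.32 ± 0.30 and Akr1b8 at 1.95 ± 0.51 (n = 4 and 5, limma adjusted p = 0.324, 0.324 and 0.486). Extracellular matrix genes were higher (none of 25 passed, 7 adjusted over the list alone, adjusted p = 9.12e-12, adjusted p = 0.0461 with an estimated correlation, median 0.30, 0.12 and 0.56 in the sets), with Col1a1 at 0.89 ± 0.22 and Lox at 1.15 ± 0.28 (both limma adjusted p = 0.342). The cell cycle list was higher with no member passing, over all genes or adjusted over the list alone (adjusted p = 6.81e-17, median 0.59, 0.50 and 0.69 in the sets), a call lost at adjusted p = 0.184 with an estimated correlation.

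Thioacetamide left 2 genes called at 5w. Pbsn, probasin, an androgen-regulated lipocalin, rose by 5.15 ± 0.75, at least 10.4-fold (n = 5 and 4, limma adjusted p = 0.00153; MC/PB signals 1.15 to 33.6), from 5.20 ± 0.57 (SD) to 10.34 ± 1.20 (SD), by 5.08 in set 1 and 5.23 in set 2. Hsd11b1, which regenerates active glucocorticoid, rose by 0.50 ± 0.09. Focus markers were higher as a list (none of 13 passed, 1 adjusted over the list alone, adjusted p = 0.0122, median 0.36, 0.30 and 0.27 in the sets), a call lost at adjusted p = 0.0595 with an estimated correlation, and Gstp1 differed by 0.25 ± 0.28. Female-biased genes were lower as a list (none of 6 passed, 2 adjusted over the list alone, adjusted p = 0.0151, median -0.74, -0.69 and -0.66 in the sets), a call lost at adjusted p = 0.0636 with an estimated correlation. At 10w 1 gene passed: Wsb1, a ubiquitin ligase subunit, fell by 1.03 ± 0.18 (n = 5 and 4, limma adjusted p = 0.0355). The stress-response gene Sesn2 stood at -0.68 ± 0.13 and the clock repressor Nr1d1 at 1.39 ± 0.35 (limma adjusted p = 0.0783 and 0.422). Interferon response genes were lower as a list (none of 22 passed, none adjusted over the list alone, adjusted p = 0.000615, median -0.28, -0.07 and -0.37 in the sets), a call lost at adjusted p = 0.672 with an estimated correlation.

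The TAA count at 5w was 0 in set 1, 1 in set 2, another gene than these, 3 with set as a block and 8 with the replicate block. It was 1 without 5w MC/PB replicate 1 or 5w TAA/PB replicate 1, 3 or 4, and 5 without 5w TAA/PB replicate 5. At 10w it was 0 in each set and 1 with set as a block. It was 0 without 10w MC/PB replicate 1, 3 or 4 or 10w TAA/PB replicate 2, 3 or 4, and 3 without 10w TAA/PB replicate 5. Without 10w MC/PB replicate 2 it was 1, a gene other than Wsb1.

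Methapyrilene changed 6 genes at 5w. The galectin Lgals2 rose by 1.42 ± 0.22, or 2.67-fold (n = 5 and 4, limma adjusted p = 0.00380), Sox4 by 1.01 ± 0.16, Rarres1 by 0.80 ± 0.14 and Hsd11b1 by 0.47 ± 0.09. The G protein regulator Rgs3 fell by 1.66 ± 0.31 and the adhesion molecule Mpzl2 by 1.10 ± 0.20. Other probe sets stood at -0.12 for Rgs3 and 0.37 to 0.78 for Sox4. Targets of p53 were lower as a list (none of 16 passed, 4 fell adjusted over the list alone, adjusted p = 0.00145, adjusted p = 0.0311 with an estimated correlation, median -0.20, -0.10 and -0.24 in the sets), with Gadd45a at -1.01 ± 0.32 and Sesn2 at -0.42 ± 0.14 (limma adjusted p = 0.337 and 0.361). Among the controls, 5w MC/PB replicate 4 stood high for the members Cdkn1a (10.28, others 9.15 to 9.23) and Ccng1 (10.4, others 9.95 to 10). Gadd45a stood at 10.81 in 5w MP/PB replicate 1 (others 8.99 to 9.37). Extracellular matrix genes were higher as a list (none of 26 passed, 2 adjusted over the list alone, adjusted p = 3.32e-05, median 0.30, 0.17 and 0.34 in the sets), a call lost at adjusted p = 0.267 with an estimated correlation. The count was 0 in set 1, 2 in set 2 and 10 with set as a block. It was 11 without 5w MC/PB replicate 1, 10 without 5w MC/PB replicate 2, 0 without 5w MC/PB replicate 3 and 2 without 5w MP/PB replicate 2 or 5w MP/PB replicate 3.

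At 10w 9 genes passed after methapyrilene, and liver carried more Nr1d1 and less of the transcription factor Onecut1. Nr1d1 rose by 2.07 ± 0.35, or 4.19-fold (n = 5 and 4, limma adjusted p = 0.00962), the transcriptional coregulator Cited2 by 0.94 ± 0.17, Pakap by 0.70 ± 0.14 and the chromatin reader Yeats4 by 0.67 ± 0.13. Onecut1 fell by 3.02 ± 0.60 (-2.26 in set 1, -3.58 in set 2), Wsb1 by 1.13 ± 0.18, Sesn2 by 0.65 ± 0.13 and Myorg by 0.52 ± 0.11 (-0.39, -0.66). Other probe sets stood at 0.07 for Yeats4, -0.08 for Myorg and -0.37 for Sesn2. The clock gene Per3 stood at 1.25 ± 0.39 (limma adjusted p = 0.362). Proteasome genes were higher as a list (none of 28 passed, none adjusted over the list alone, adjusted p = 2.15e-07, median 0.14, 0.14 in both sets), a call lost at adjusted p = 0.754 with an estimated correlation. The count was 0 in set 1, 2 in set 2 and 11 with set as a block. It was 1 without 10w MC/PB replicate 2 or 10w MP/PB replicate 1, 3 without 10w MP/PB replicate 2 or 10w MP/PB replicate 4, 4 without 10w MC/PB replicate 3 or 10w MC/PB replicate 4, and 14 without 10w MP/PB replicate 3.

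Acetaminophen left no called gene at 5w: limma gave 0, with 755 at an unadjusted p under 0.05, and 2 with set as a block and 2 with the replicate block. Cell cycle genes were higher as a list (none of 36 passed, 3 adjusted over the list alone, adjusted p = 7.66e-09, median 0.28, 0.10 and 0.49 in the sets), a call lost at adjusted p = 0.240 with an estimated correlation. Cyclin D1, Ccnd1, stood at 0.87 ± 0.25, the thymidine kinase Tk1 at 0.53 ± 0.15 and Mki67 at 0.70 ± 0.24 (n = 4 per group, limma adjusted p = 0.288, 0.288 and 0.466). NRF2 targets were higher as a list (none of 18 passed, 1 adjusted over the list alone, adjusted p = 0.000986, median 0.17, 0.18 and 0.24 in the sets), a call lost at adjusted p = 0.0637 with an estimated correlation. Set 1 alone gave 0 genes and set 2 alone 4, and 6 passed without 5w APAP/PB replicate 1.

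At 10w 7 genes passed after acetaminophen. Nr1d1 rose by 2.14 ± 0.37, or 4.40-fold (n = 4 per group, limma adjusted p = 0.00858), the immediate early gene Ier3 by 1.12 ± 0.21, the stress kinase Map3k1 by 1.04 ± 0.17 and Baiap2l1 by 0.79 ± 0.14. Tat, tyrosine aminotransferase, fell by 1.39 ± 0.25 (-1.03 in set 1, -1.75 in set 2), Wsb1 by 0.97 ± 0.19 and Sesn2 by 0.83 ± 0.14 (-0.47 by another probe set). The clock genes Dbp and Cry1 stood at 1.85 ± 0.49 and -0.89 ± 0.23 (limma adjusted p = 0.270 and 0.242). Fatty acid oxidation genes were lower as a list (none of 24 passed, 2 adjusted over the list alone, adjusted p = 1.26e-05, median -0.15, -0.12 and -0.23 in the sets), a call lost at adjusted p = 0.239 with an estimated correlation. Neither set alone called a gene, and 7 passed with set as a block. The count was 3 without 10w MC/PB replicate 1 or 10w MC/PB replicate 2 and 0 without 10w APAP/PB replicate 2.

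Some called genes were shared between initiators, all of them measured against the same MC/PB arrays. Adam8 and Pvt1 rose after both doses of diethylnitrosamine at 5w, Sox4 rose after DEN30 and MP, and Hsd11b1 after TAA and MP. At 10w Wsb1 fell after TAA, MP and APAP, and Nr1d1 rose and Sesn2 fell after MP and APAP. In TAA these 2 stood in the same directions without passing, as given above. The fold changes of 10 pairs of initiators correlated with a median r of 0.550 at 5w and 0.538 at 10w, against 0.530 and 0.531 in simulated unchanged groups. The median covariance was 0.0290 against 0.0207 and 0.0288 against 0.0222. With the MC/PB arrays split between the effects, the median r was 0.106 and 0.094. Gstp1 was the gene called after DEN30 at both weeks.

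The last question was how livers changed between the weeks, with hepatectomy between the samples. The main fit, as planned, did not pair both samples of an animal. Counts with the animal as a block, which were larger here, are given beside it. Without phenobarbital 5 of 10910 genes passed: Lurap1l rose by 1.67 ± 0.31, or 3.17-fold (n = 4 per group, limma adjusted p = 0.0149), the lymphocyte growth factor Il7 by 1.42 ± 0.27 (1.13 in set 1, 1.70 in set 2), Fam117b by 0.72 ± 0.15 and Plekhf1 by 0.62 ± 0.13, and the endothelial Emcn fell by 0.62 ± 0.13 (-0.76, -0.48). Endothelial genes were lower as a list (1 of 16 fell, 2 adjusted over the list alone, adjusted p = 1.49e-06, median -0.27, -0.34 and -0.14 in the sets), a call lost at adjusted p = 0.0782 with an estimated correlation. The count was 14 with set as a block, 23 with the replicate block and 154 with the animal as a replicate block, and 0 in each set alone. It was 0 without 5w MC/water replicate 2, 10w MC/water replicate 2 or 10w MC/water replicate 4, 4 without 10w MC/water replicate 1, none of them among the 5, 2 without 5w MC/water replicate 3, 3 without 5w MC/water replicate 4, and 11 without 10w MC/water replicate 3.

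Under phenobarbital 143 genes passed between the weeks, 93 higher and 50 lower at 10w. The cytochrome Cyp2a3 rose by 4.06 ± 0.86, at least 6.35-fold (n = 4 per group, limma adjusted p = 0.00774; 5w signals 2.31 to 40.9; 5.41 in set 1, 2.72 in set 2), Lpl by 2.50 ± 0.42, Cyp4a8 by 2.33 ± 0.46, Sds by 2.23 ± 0.49, Ddit4l by 2.15 ± 0.41 and Gsta3 by 1.61 ± 0.35. Obp3 fell by 2.27 ± 0.45, the secreted phospholipase Pla2g2a by 1.79 ± 0.49, Oat by 1.55 ± 0.36, Arrdc3 by 1.52 ± 0.38 and Ier3 by 1.14 ± 0.26. For Pla2g2a the lower bound was only 1.35-fold, with 10w signals of 5.72 to 54.9. Tsc22d1 fell by 1.30 ± 0.29 and the endothelial receptor Kdr by 0.42 ± 0.09. Other probe sets of these genes did not show the fall, at 0.25 and 0.04 for Tsc22d1 and 0.04 for Kdr (limma adjusted p = 0.797, 0.989 and 0.989). Heat shock genes were higher as a list (3 of 15 rose, 6 adjusted over the list alone, adjusted p = 2.79e-08, median 0.41, 0.39 and 0.34 in the sets), a call lost at adjusted p = 0.0560 with an estimated correlation. Called members were the small chaperone Cryab at 1.77 ± 0.44, Hsph1 at 0.76 ± 0.20 and Chordc1 at 0.61 ± 0.14. Phenobarbital-inducible genes were higher too (2 of 21 rose, 6 adjusted over the list alone, adjusted p = 3.16e-07, median 0.37, 0.47 and 0.37 in the sets), a call lost at adjusted p = 0.0560 with an estimated correlation. The count was 209 with set as a block, 250 with the replicate block, 528 with the animal as a replicate block, 0 in set 1 and 9 in set 2. It was 35 without 5w MC/PB replicate 3 or 10w MC/PB replicate 2, 62 without 10w MC/PB replicate 1, 68 without 5w MC/PB replicate 2 and 90 without 10w MC/PB replicate 4.

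Whether an effect itself differed between the weeks was tested in the same model. Limma called 0 genes in each of 6 such tests, with 490 for PB, 246 for DEN3, 216 for DEN30, 260 for TAA, 388 for MP and 357 for APAP at an unadjusted p under 0.05, and 0 in each set alone and with set as a block. With the animal as a replicate block, limma called 7 genes for PB, among them Phgdh, the first enzyme of serine synthesis, at 2.96 ± 0.49, Lpl at 2.39 ± 0.45 and Akr7a3 at 1.32 ± 0.29 (adjusted p = 0.00159, 0.00892 and 0.0494). It called 1 each for TAA (Pbsn, -3.94 ± 0.74), MP (Mpzl2, 1.30 ± 0.25) and APAP (Map3k1, 0.94 ± 0.18), and none for DEN3 or DEN30. Phgdh was named after its value was seen. Without the animal block, Gsta3 differed by 1.30 ± 0.49 and Obp3 by -2.24 ± 0.63 for PB (limma adjusted p = 1 and 0.676), and Gstp1 by 1.07 ± 0.53 for DEN30 (limma adjusted p = 1). The PB count was 1 without 5w MC/water replicate 2 or without 5w MC/PB replicate 2.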

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

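The tests in this part were planned, except that those within an array set were chosen only after the data were seen, as were the gene lists and named genes singled out from the results. A single animal stood apart from its group, by the gap between it and the nearest other animal relative to the whole range, in 21 of 339 combinations of gene and group (6.19%); chance gives about 1 in 20. All values are log2 signals.

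In 5w MC/PB, replicate 4 stood apart for Cdkn1a at 10.28 (others 9.15 to 9.23), Ccng1 at 10.40 (9.95 to 10.00), Pkia at 6.84 (7.28 to 7.31) and Klf6 at 9.31 (9.08 to 9.11), and replicate 1 for Prps2 at 9.63 (9.29 to 9.32) and Pla2g2a at 6.17 (7.46 to 7.72). Both p53 targets in this animal lay above the rest of the control group that the initiators are compared with. In 10w MC/PB, Gpx2 stood at 10.15 in replicate 2 (others 5.86 to 6.26), Cyp4a1 at 11.44 in replicate 3 (12.06 to 12.07) and Col1a1 at 7.94 in replicate 1 (8.47 to 8.57). In MC/water, Ces2c stood at 9.27 (8.82 to 8.86) and Fam117b at 9.43 (9.61 to 9.63) in 5w replicate 3, Lurap1l at 10.36 in 10w replicate 3 (11.63 to 11.65) and Kdr at 11.88 in 10w replicate 2 (11.59 to 11.64).

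In the DEN groups, Akr1b8 stood at 5.87 in 5w DEN3/PB replicate 5 (others 7.18 to 7.53), Lox at 6.80 in 10w DEN3/PB replicate 1 (7.19 to 7.33), Mdm2 at 10.45 in 10w DEN3/PB replicate 5 (10.15 to 10.18) and Il13ra2 at 8.95 in 10w DEN30/PB replicate 2 (8.36 to 8.42). In the MP groups, Rarres1 stood at 12.85 in 5w replicate 4 (13.21 to 13.30), Gadd45a at 10.81 in 5w replicate 1 (8.99 to 9.37), Gstp1 at 10.70 in 10w replicate 5 (9.55 to 9.82) and Cdkn1a at 10.55 in 10w replicate 5 (10.08 to 10.12).

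By camera's test of the difference between the weeks, 7 of 32 lists passed for PB, 8 for DEN3, 1 for DEN30, 1 for TAA, 4 for MP and 6 for APAP. With an estimated correlation 1 held for DEN3 and 1 for MP, and 0 for the others. The 4 given here were picked after their results were seen and include both that held. NRF2 targets responded more to phenobarbital at 10w (median difference 0.44, adjusted p = 2.80e-05, lost at adjusted p = 0.252 with an estimated correlation, medians 0.43 and 0.39 within the array sets). Targets of p53 were relatively lower at 10w after DEN3 (median -0.17, adjusted p = 0.00241, adjusted p = 0.0207 with an estimated correlation; -0.18 and -0.16), where Cdkn1a differed by -0.99 ± 0.29 (limma adjusted p = 1). Targets of p53 were relatively higher at 10w after MP (median 0.17, adjusted p = 0.00901, adjusted p = 0.0420 with an estimated correlation; 0.14 and 0.22). Both p53 results use 5w MC/PB replicate 4 as one of the controls. Cell cycle genes were relatively higher at 10w after DEN30 (median 0.62, adjusted p = 4.69e-14, lost at adjusted p = 0.528 with an estimated correlation; 0.62 and 0.60), where Cdk1 differed by 1.01 ± 0.50 (limma adjusted p = 1).

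Probe sets with no or several gene symbols, which the comparisons of genes leave out, were tested in the same way in limma, 4406 at 5w and 4395 at 10w. Called were 15 for PB, 6 for DEN3, 3 for DEN30, 1 for TAA, 2 for MP and 1 for APAP at 5w, and 58 for PB, 3 for TAA, 4 for MP and 4 for APAP at 10w. A probe set with no symbol was the TAA call, 1 of the MP calls and the APAP call at 5w (1.12, 1.08 and 1.10). At 10w another was called in TAA, MP and APAP (2.59, 3.14 and 3.14), as was 1 more (2.33, 2.94 and 3), and 1 was called in MP and APAP (2.52 and 2.43). All are measured against the same MC/PB arrays. One of the PB calls, a Cyp2b probe set that matches several genes, differed by 3.69 ± 0.29 at 5w and 4.14 ± 0.25 at 10w under phenobarbital (limma adjusted p = 8.39e-10 and 1.62e-12). Its signal lay between 906 and 6339 in MC/water at 5w and between 799 and 3768 at 10w, and between 34389 and 51164 in the phenobarbital groups.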

How the results depend on the processing

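The tests within an array set, or with the set as a block, were chosen only after the data were seen; the others were planned. The cause was not tested for the shifts below, except that a fit of 1 array set holds 2 or 3 arrays per group and a fit of the compared groups holds fewer arrays. The offset and filter set how signals near background count.

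Without an offset the count for time in MC/water was 10 and for PB by time 1. Without a filter TAA at 5w gave 1, the DEN dose at 5w gave 5 and DEN3 at 10w gave 0. Under quantile normalization DEN3 at 10w gave 1, DEN30 at 10w gave 1, TAA at 10w gave 0 and time in MC/water gave 10, and Gstp1 in APAP at 5w reversed from 0.00 to 0.01. With all probe sets DEN3 at 5w gave 11, APAP at 5w gave 1, DEN3 at 10w gave 0, TAA at 10w gave 4, MP at 10w gave 15 and APAP at 10w gave 13. With only the groups compared PB at 5w gave 78, DEN3 at 5w gave 0, DEN30 at 5w gave 4, TAA at 5w gave 1, the DEN dose at 5w gave 3, DEN3 at 10w gave 0, DEN30 at 10w gave 6 and TAA at 10w gave 3. With an estimated correlation 25 list calls passed in place of 171.

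With the replicate block DEN3 at 5w gave 8, TAA at 5w gave 8, APAP at 5w gave 2, the DEN dose at 5w gave 2, PB at 10w gave 394, DEN3 at 10w gave 0, time in MC/water gave 23 and time in MC/PB gave 250; it moved no other count by more than 1.5 times. With the animal as a replicate block time in MC/water gave 154, time in MC/PB gave 528, PB by time gave 7, and TAA, MP and APAP by time gave 1 each.

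With the array set as a block MP at 5w gave 10, APAP at 5w gave 2, the DEN dose at 5w gave 5, PB at 10w gave 370 and time in MC/water gave 14. Within array set 1, PB at 5w gave 18, DEN30 at 5w gave 1, PB at 10w gave 54, the genes called under PB at both weeks numbered 12, and DEN3, TAA and MP at 5w, DEN3, TAA, MP and APAP at 10w and both changes between weeks gave 0. Within array set 2, PB at 5w gave 20, DEN3 at 5w gave 2, DEN30 at 5w gave 0, TAA at 5w gave 1, MP at 5w gave 2, APAP at 5w gave 4, PB at 10w gave 34, DEN30 at 10w gave 1, MP at 10w gave 2, time in MC/PB gave 9, the genes called under PB at both weeks numbered 15, and DEN3, TAA and APAP at 10w and time in MC/water gave 0. Uncalled values that reversed within set 1 were Gstp1 in APAP at 5w (0.11), Gstp1 in TAA at 10w (-0.10), Ggt1 in TAA at 10w (-0.04) and Ggt1 in APAP at 10w (-0.13). Within set 2 they were Ggt1 in DEN3 at 10w (-0.02) and Gstp1 in MP at 10w (0.21). The uncalled clock list in APAP at 10w, higher by camera with all arrays (mean 0.23, median -0.07), was lower by camera within set 1 (median -0.01), and its median was 0.09 within set 2. The clock list in MP at 10w had a median of 0.02, and of -0.01 within set 2.

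Leaving out 1 array at a time gave counts at 5w from 65 to 136 for PB, 2 to 6 for DEN3, 2 to 13 for DEN30, 1 to 5 for TAA, 0 to 11 for MP, 0 to 6 for APAP and 0 to 2 for the DEN dose. At 10w they ran from 141 to 179 for PB, 0 to 1 for DEN3, 0 to 3 for DEN30, 0 to 3 for TAA, 1 to 14 for MP, 0 to 10 for APAP and 0 to 1 for the DEN dose. They ran from 0 to 11 for time in MC/water, 35 to 138 for time in MC/PB and 0 to 1 for PB by time, stayed at 0 to 0 for the other effects by time, and ran from 42 to 72 for genes called under PB at both weeks, 74 with all arrays, with the lowest without MC/PB replicate 1. Uncalled genes whose sign changed on leaving out an array ran from -0.31 to 0.12 (Ggt1 in DEN3 at 5w), -0.13 to 0.12 (Gstp1 in APAP at 5w), -0.01 to 0.38 (Gstp1 in PB at 10w), -0.01 to 0.38 (Gstp1 in TAA at 10w), -0.36 to 0.10 (Gstp1 in MP at 10w), -0.01 to 0.29 (Ggt1 in MP at 10w) and -0.37 to 0.06 (Gstp1 in APAP at 10w).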

Other observations

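The tests of RNA integrity, of animal numbers, of probe sets above a common minimum size, of the clock genes' phase and of the control group behind Nr1d1 were chosen only after the results were seen, and the bound for the split MC/PB arrays was refined after a first outcome.

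The exocrine pancreas list, which has 2 measured members, was lower after DEN30 at 5w (median -1.31; -1.31 and -1.32 within the array sets; 1 fell over all genes, 2 adjusted over the list alone, adjusted p = 4.58e-06, adjusted p = 0.000619 with an estimated correlation), with Cela1 among them. Antigen presentation genes were higher after DEN30 at 10w (none of 15 passed, none adjusted over the list alone, median 0.35, adjusted p = 0.000908, lost at adjusted p = 0.223 with an estimated correlation). Proteasome genes were higher after APAP at 5w (none of 28 passed, none adjusted over the list alone, median 0.12, adjusted p = 7.13e-07, lost at adjusted p = 0.0769 with an estimated correlation). Circadian clock genes were lower as a list between the weeks in MC/PB (none of 17 passed, 2 higher and 3 lower adjusted over the list alone, median -0.26, adjusted p = 0.0297, lost at adjusted p = 0.0560 with an estimated correlation).

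The arrays of every group fell into a pair of sets. The sets were read from the same values, so that a count of genes different between them is partly built in, but they also followed the labels: in 14 of 14 groups animals 1 and 3 lay in set 1 and animals 2 and 4 in set 2, and both samples of each of 31 animals lay in the same set. By number alone, 3533 of 10910 genes differed between animals 1 and 3 and animals 2 and 4 (56 arrays, limma), against 22 and 21 for the other ways to part the 4 numbers. These fits took both samples of an animal as separate arrays, which overstates the number of replicates in all 3. Probe sets that respond to the hybridisation and not to the RNA of the gene would differ in sign within a gene. Of 1283 genes different between the sets with a next brightest probe set, it had the same sign in 62.4% (Wilson 95% interval 59.7 to 65.0), against 95.7% (88.0 to 98.5) of 69 genes changed by phenobarbital at 10w. The differences between sets were smaller. Among genes that differed by at least 0.5, the shares were 72.6% (62.3 to 81.0) of 84 and 94.7% (85.6 to 98.2) of 57. This limit is a minimum only, so sizes above it are not matched. Both shares between the sets lie above 50%, so such probe sets need not account for all of the difference, and a difference of the animals or of their handling stays open. A difference in RNA integrity would move the actin ratio of 3 prime to 5 prime signal with that of GAPDH, but their log2 differences between the sets were -0.03 (-0.08 to 0.02, exact sign-flip p = 0.188) and 0.14 (0.10 to 0.18; higher in 7 of 7 treatments, exact sign-flip p = 0.0156), which argues against it. The labels name no batch, and no biological explanation was tested.

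Nr1d1 was higher after MP and APAP than in MC/PB at 10w. An unusual MC/PB group is argued against as the whole source, since Nr1d1 was also higher by 1.17 than in the DEN3, DEN30 and TAA animals together (9 against 14 animals). These 2 groups were picked as the highest; with the 2 highest of 5 groups chosen anew in each of 20000 permutations, permutation p = 0.00215. In the 5w samples of the same animals the difference was 0.91 (exact permutation p = 9.54e-05). Both samples of an animal correlated (consensus 0.315), so the 5w values are not independent of that choice, and this p does not allow for it. An unusual MC/PB group stays open for part of the difference, as MC/PB had the lowest mean of the phenobarbital groups (7.23, against 7.80 in DEN30, 7.97 in DEN3, 8.62 in TAA, 9.30 in MP and 9.37 in APAP), and TAA stood between. At 5w the means were 8.64 in MP, 8.72 in APAP and 7.86 in MC/PB. Another hour of sampling cannot be told apart: a phase index of 8 other clock genes was higher by 1.01 than in MC/PB (9 against 4 animals, exact permutation p = 0.0545), and the labels give no hour. At 10w the mean index was -1.33 (SD 0.8) in MP and -1.18 (SD 1) in APAP, and between -2.3 and -1.93 in the other phenobarbital groups. At 5w it was -1.75 in MP and -1.77 in APAP, and between -2.49 and -2.14 in the others. These differences from the other initiators were not tested. An effect of the initiators themselves stays open, untested.

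The fold changes of the initiator effects correlated at both weeks, and the shared MC/PB arrays are a candidate source. With the MC/PB arrays split between the effects, the median r fell to 0.106 at 5w, within the range of -0.208 to 0.115 in 1000 draws of resampled unchanged groups, and to 0.094 at 10w, within -0.193 to 0.135. The 5w value is borderline: with the first 100 draws the upper bound was 0.105, or 0.1 without adjusting for array set, so that the value lay just above it. The adjustment and the larger number of draws were chosen after that outcome, and the error of the later bound was 0.005. A small response common to the initiators at 5w may therefore be present and stays open.

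Each comparison was repeated on other splits of the same animals into groups of the same sizes. Over all splits, without regard to pairs of animals, the share was under 0.05 for the following counts. The shares were not adjusted over the 22 comparisons, and with 35 splits none can lie below 0.0286. A share under 0.05 therefore does not exclude chance for a single comparison. At 5w, 1 of 35 splits, the real one, gave as many genes for PB (131; highest other 0), 1 of 100 for DEN3 (4; 2), 1 of 35 for DEN30 (12; 8), 3 of 100 for TAA (2; 5) and 1 of 100 for MP (6; 2). At 10w the numbers were 1 of 35 for PB (238; highest other 0), 1 of 35 for DEN30 (3; 0), 2 of 100 for MP (9; 9) and 1 of 35 for APAP (7; 1). Between the weeks they were 1 of 35 in MC/water (5; 3) and 1 of 35 in MC/PB (143; 14). The share was not under 0.05 for the DEN dose at 5w (5 of 100, real 1, highest other 3), for DEN3 at 10w (5 of 100, real 2, highest other 4) or for TAA at 10w (5 of 100, real 1, highest other 2). In the first a split along the array sets gave 3, and in DEN3 at 10w one gave 4; with the set as a block the real counts were 5 and 2. For counts of 0 every split was as large: 35 of 35 for APAP at 5w (highest other 1), 100 of 100 for the DEN dose at 10w (1), 35 of 35 by time for PB, DEN30 and APAP (0 each), and 100 of 100 by time for DEN3 (0), TAA (1) and MP (1). The 2 samples of an animal pair the comparisons between weeks. Within a week the same number names different animals, so the design holds no pairs there. Same-numbered animals still correlated above 0.1 in all others listed but MP and APAP at 5w, and most of this went with the array set. With same numbers taken as pairs all the same, between 8 and 15 splits parted as many pairs as the real one, too few for a share under 0.05 in any comparison, so the shares over all splits do not settle chance where pairs matter. Among these, only the real split gave as many genes for PB at both weeks, DEN30 at both weeks, the DEN dose at 5w, DEN3 and APAP at 10w and time in MC/water (highest other 0 each), for MP at 10w and time in MC/PB (1 each) and for DEN3 at 5w (2). For TAA 3 of 13 were as large at 5w (highest other 5) and 2 of 8 at 10w (1).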
